A study of Arabidopsis thaliana with 32 samples.

How the data were processed

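Two-colour cDNA arrays were used to compare RNA from dexamethasone-treated and mock-treated Arabidopsis thaliana callus that carried 35S:LFY-GR. LEAFY (LFY) is a transcription factor that specifies floral meristem identity. In the fusion it is joined to the hormone-binding part of the glucocorticoid receptor, so that the steroid dexamethasone controls its entry into the nucleus, and the 35S promoter drives it in most tissues. Per the labels, the tissue came from root explants, and the array was a cDNA array enriched for transcripts of flowers. The series holds 32 arrays, 4 at each of 8 time points (0, 2, 4, 6, 8, 10, 12 and 22 h). Each array carried treated and control RNA of 1 time point. On replicates 1 and 3 the treated RNA was in channel 2, and on replicates 2 and 4 it was in channel 1, per the labels. The labels do not say whether the 4 arrays of a time point came from 4 pairs of RNA samples or from dye swaps of 2 pairs. The p-values therefore measure the spread between arrays, which may be technical.

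The deposited values were log10 ratios, 1 per feature and array, for 10816 features. The labels name Rosetta Resolver as the authors' analysis software. The background correction, the normalization, the numerator of the ratio and the dyes are not given in the sources used here. The scale was inferred from the values, as the array medians lay between 0.00092 and 0.0152 and the extreme values were exactly -2 and 2, which is a ratio of 100 in either direction. No scanner files were used here, so neither the signal over background nor the centring step could be examined. Arrays had values for 10646 to 10809 features, and the number of arrays limits the precision. Values at the limits made up 0.982% of all values, 2733 at the upper and 648 at the lower limit, and they were kept in the main setting.

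The log10 ratios were multiplied by 3.32 to give log2 ratios. Whether the authors had already turned the swapped arrays was read from correlations across features, with limit values left out. At 2, 4, 6, 8, 10, 12 and 22 h the mean correlation was 0.147, 0.120, 0.163, 0.206, 0.161, 0.335 and 0.285 between arrays of the same orientation. Between arrays of opposite orientation it was -0.0187, -0.161, -0.109, -0.0642, -0.154, -0.294 and -0.255, with single pairs up to 0.0848 at 2 h and 0.0455 at 8 h. At 0 h both were positive, 0.177 and 0.169. With limit values kept, as in the fit, the means at 10 h ran the other way (-0.0860 and 0.0788), and at 2 h both were below 0 (-0.0447 and -0.000675). The ratios of replicates 2 and 4 were therefore turned. The positive side below is treated over control if the deposited ratio was channel 2 over channel 1. That reading is likely by the usual convention only. If the ratio was channel 1 over channel 2, all signs exchange, and the counts and sizes stay as given. Limit values were also left out for pairs of arrays of 1 orientation at different time points. The lowest correlation among them was -0.311, between replicate 1 at 0 h and replicate 1 at 2 h. The direction is not settled, because no source used here states the numerator.

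The features carry plate positions as identifiers. None of them matched the gene table of assembly TAIR10.1, and 0 features have a gene name. The 15 gene lists fixed before the data were examined could not be tested, nor could features be averaged by gene. Several features may hold clones of 1 transcript, so counts of features are not counts of genes.

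A linear model was fitted to the log2 ratios of all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had 1 coefficient per time point and 1 dye term per feature, with 23 residual degrees of freedom for features with all values. Features needed at least 1 value per orientation at each time point, which left 10732. Two-sided tests were made of the ratio against 0 at each time point, of the mean of 2 to 22 h minus 0 h, of the mean of 10, 12 and 22 h minus the mean of 2, 4 and 6 h, and, as an F test, of the 7 differences from 0 h. P-values were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05. All adjusted p-values of single features come from limma. The medians of a feature set per array were compared between time points by exact two-sided permutation tests of 4 arrays against 4. Their smallest possible p is 0.0286, from 70 splits. Identifiers were to be named at most 2 each way where no gene names existed. The model, its tests and that limit were fixed before the data were examined. The 2 largest positive and the 2 largest negative values of the mean of 2 to 22 h minus 0 h past the threshold were taken, a choice of comparison made once it was seen that no feature had a gene name. The feature sets followed over time and the tests of their medians were chosen after the data had been seen.

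The fit was tested on simulated data. The simulated noise was normal and independent between arrays, with no values held at the limits and with changes placed at 22 h only. The rates below therefore do not cover limit values or errors shared between arrays. For the test at 22 h against 0 over 10732 features, 45.1% of features changed by 0.5 on the log2 scale were recovered, 87.3% of those changed by 1 and 92.1% of those changed by 2. Of 153 calls, 10 were false (6.54%).

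Alternatives were a model with no dye term, the replicate number as a block, replicates 1 and 2, and 3 and 4, averaged or as a random block, centring or scaling of arrays, features with values on all 32 arrays, a robust variance, a threshold of 0.01, each time point fitted alone, each replicate left out, each later time point left out, and the sign turned. For counts at a time point, a replicate left out means the 1 array of that number at that time point. For the F test, the contrasts over time and the named features, it means all arrays of that number. Limit values left out, the 10 arrays with over 100 upper-limit values left out, and features with values in 1 orientation let in were added after the data had been seen. Figures were drawn with matplotlib in Python 3.11.15.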

Results

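Expression was measured on 32 two-colour cDNA arrays in callus with an inducible LEAFY protein, with 4 arrays at each of 0, 2, 4, 6, 8, 10, 12 and 22 h. The series is a time course, so the comparisons made were treated against control RNA at each time point, the later time points against 0 h, and late against early time points. Each array had a value for 10646 to 10809 of the 10816 features, and 10732 features were tested. Values are log2 ratios. The positive side is dexamethasone over control if the deposited ratio was channel 2 over channel 1, which is likely by convention but not stated. All signs exchange if it was not. Features have plate positions and no gene names, so they are described as groups, and 4 are named.

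At 0 h, limma called 0 features, with 302 (2.81%) at an unadjusted p under 0.05. The number of features whose ratio differed from 0 was 29 at 2 h, 187 at 4 h, 308 at 6 h, 334 at 8 h, 335 at 10 h, 302 at 12 h and 610 at 22 h. The positive side held 16 of the 29 features at 2 h and 104 of the 187 at 4 h. It held 209 features at 6 h, 249 at 8 h, 239 at 10 h, 248 at 12 h and 444 at 22 h, against 99, 85, 96, 54 and 166 on the negative side. All 29 features called at 2 h had the same sign on every array of that time point, as did 557 (91.3%) of those called at 22 h. Without replicate 2 at 2 h, limma called 0 features there, with 459 at an unadjusted p under 0.05. With replicates 1 and 2, and 3 and 4, averaged as if they were dye swaps, the counts at 2, 4 and 22 h were 2, 20 and 358. The negative side alone moved further, to 0 features at 4 h with the arrays averaged (478 at an unadjusted p under 0.05 by limma), where it held 18 at 6 h, 24 at 8 h, 27 at 10 h, 9 at 12 h and 60 at 22 h. With 1 replicate left out it ran from 16 (without replicate 1) to 63 features at 4 h, from 50 (without replicate 1 or 4) to 61 at 6 h, from 32 (without replicate 2) to 132 (without replicate 4) at 8 h, from 33 (without replicate 1) to 92 at 10 h, from 18 (without replicate 1) to 42 at 12 h and from 61 (without replicate 1) to 250 (without replicate 4) at 22 h. With the replicate block the negative side held 41, 125, 202, 184, 170, 122 and 328 features at 2 to 22 h, and with the arrays scaled 44, 94, 30, 69, 65, 117 and 77.

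**Figure D1:**
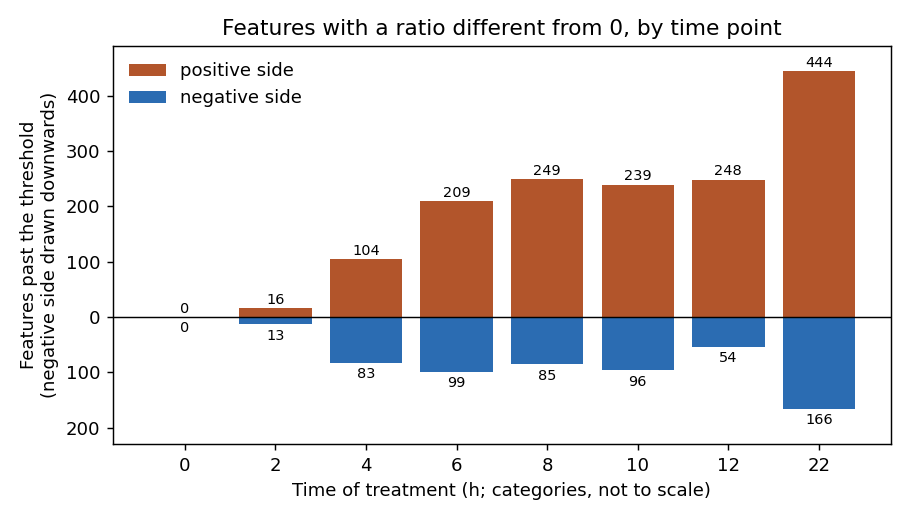
Number of features past the adjusted threshold of 0.05 (vertical axis) at each time of treatment in hours (horizontal axis, categories), with the positive side drawn upwards and the negative side downwards. The positive side grew from 16 features at 2 h to 444 at 22 h, and the negative side was smaller at every later time point.

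The sizes of the ratios differed between the sides. At 22 h, 138 positive and 15 negative features lay beyond 2-fold, and 53 positive and 0 negative features lay beyond 4-fold. The median log2 ratio of the called features at 22 h was 0.78 on the positive side and -0.52 on the negative side. At 4 h, 25 positive and 7 negative features lay beyond 2-fold. At 8 h, 1 positive and 10 negative features lay beyond 4-fold, and 11 of the 334 features called at that time had a value at the limit.

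Values at the limits were unevenly spread over the arrays. Of the 32 arrays, 10 had 112 to 476 features at the upper limit and 7 to 25 without a value, and the other 22 had 0 to 62 at the limit and 35 to 170 without a value. Of the 10 arrays, 6 had the treated RNA in channel 2 and 4 in channel 1. All of the 10 except replicate 3 at 4 h were replicates 1 or 2.

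**Figure D2:**
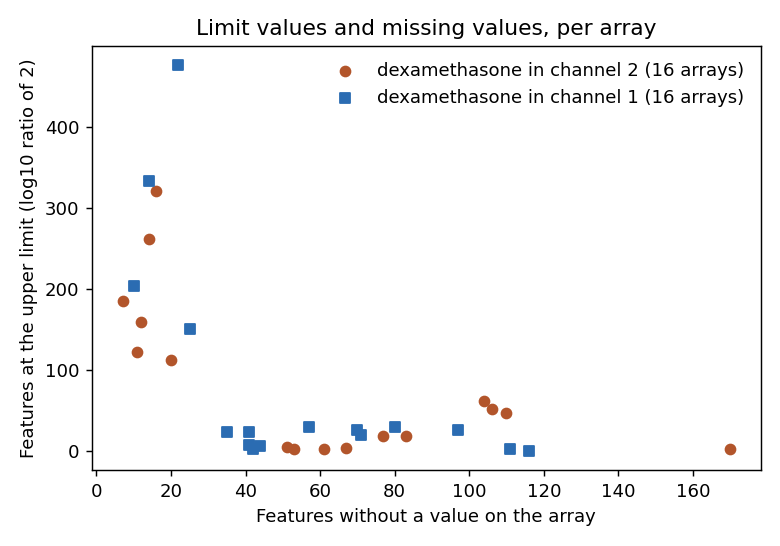
Number of features at the upper limit, a log10 ratio of 2 (vertical axis), against the number without a value (horizontal axis). Each point is 1 of the 32 arrays, circles with the treated RNA in channel 2 and squares with it in channel 1. The 10 arrays with over 100 features at the limit all have 25 or fewer features without a value.

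The 444 features on the positive side at 22 h were followed back in time. Their median log2 ratio per array was 0.01 ± 0.03 (SD, n = 4) at 0 h, 0.12 ± 0.08 at 2 h, 0.24 ± 0.07 at 4 h, 0.36 ± 0.06 at 6 h, 0.44 ± 0.10 at 8 h, 0.49 ± 0.08 at 10 h, 0.48 ± 0.07 at 12 h and 0.77 ± 0.11 at 22 h. For the 166 features on the negative side it was -0.01 ± 0.10 at 0 h, -0.17 ± 0.04 at 2 h, -0.21 ± 0.07 at 4 h, -0.23 ± 0.12 at 6 h, -0.21 ± 0.10 at 8 h, -0.34 ± 0.11 at 10 h, -0.35 ± 0.11 at 12 h and -0.54 ± 0.23 at 22 h. Each later time point differed from 0 h in both sets (exact permutation test, p = 0.0286, n = 4 per group, adjusted p = 0.0308 over 14 tests) except the negative set at 8 h (exact permutation p = 0.0571, adjusted p = 0.0571). For the positive set, the steps from 4 to 6 h and from 12 to 22 h each had an exact permutation p of 0.0286, which did not pass over the 8 steps tested (adjusted p = 0.114). These permutation tests take the 4 arrays of a time point as independent, and their p-values are too small if the arrays are dye swaps of 2 RNA pairs. At 22 h the negative set stood at -0.78 and -0.68 on replicates 1 and 2, and at -0.39 and -0.29 on replicates 3 and 4. The sets were chosen at 22 h, so the 22 h values and the tests that use them are not independent of the choice. With the features called on 3 arrays at 22 h and read on the fourth, the medians were 0.77 ± 0.11 on the positive side and -0.22 ± 0.16 on the negative side (SD over the 4 arrays read). If replicates 1 and 2, and 3 and 4, are dye swaps of the same RNA, the swap of the array read stayed in the calling fit. The array read is then not independent of the choice either.

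**Figure D3:**
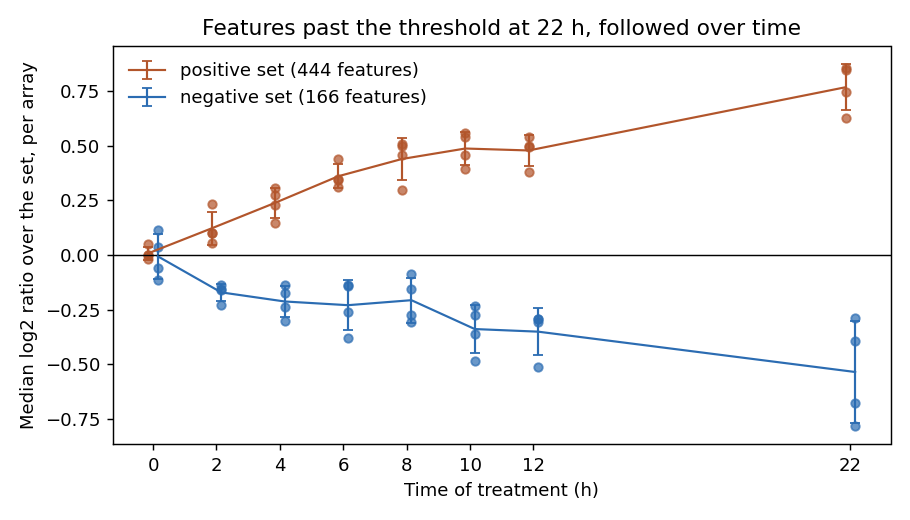
Median log2 ratio over the features called at 22 h (vertical axis) against time of treatment in hours (horizontal axis). Points are arrays, and lines with bars give the mean and SD of 4 arrays. The positive set of 444 features stands at 0.12 at 2 h and 0.77 at 22 h, and the negative set of 166 features at -0.17 and -0.54.

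Features called at one time point were often called at others. Of the 16 positive features at 2 h, 15 were shared with the positive calls of each other later time point. The positive calls at 12 h and 22 h shared 221 of the 248 features at 12 h, where independent lists would share 10.3, and the negative calls shared 33 of 54, against 0.835. Between 4 h and 22 h the positive calls shared 72 of 104, against 4.30, and the negative calls 23 of 83, against 1.28. The time points have no arrays in common, but they share the dye term and the variance estimate of each feature. Across all time points 942 features were called at least once, of which 507 were called at 1 time point, 219 at 4 or more, and 5 on opposite sides at different times.

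The mean of 2 to 22 h minus 0 h, which takes the 0 h arrays as the background, differed from 0 for 136 features on the positive and 34 on the negative side. Their median differences were 0.85 and -0.61. The negative side fell to 15 and 14 features without replicate 1 or 2 and to 3 with the arrays averaged, and rose to 79 with the replicate block. Against 0, without subtracting 0 h, 945 features were positive and 765 negative. That test is more precise, as it holds no error of the 0 h arrays, so its counts are not directly comparable with 136 and 34. On the positive side, feature GP005B2 had a value of 2.22 (SE 0.49, adjusted p = 0.0119) and GP088H4 one of 2.06 (SE 0.39, adjusted p = 0.00295). Their order is not settled, since without replicate 2 the values were 2.00 and 2.23. GP005B2 stood at -0.02 ± 0.45 (SD, n = 4) at 0 h, 2.09 ± 0.43 at 6 h and 3.82 ± 0.37 at 22 h. At 8 h, 1 of its arrays was at the limit, and its mean there was 2.81 ± 2.71. GP088H4 stood at -0.24 ± 0.17 at 0 h, 1.301 ± 0.457 at 2 h (adjusted p = 0.163) and 2.46 ± 1.16 at 22 h. On the negative side, GP089G2 had a value of -1.37 (SE 0.17, adjusted p = 1.53e-05). Its ratio was 0.31 ± 0.27 at 0 h, -0.81 ± 0.27 at 2 h, -1.40 ± 0.15 at 6 h and -0.73 ± 0.49 at 22 h. GP033F4 had the most negative value, -2.98 (SE 0.61, adjusted p = 0.00703), which came from the 0 h arrays, where 3 arrays gave 2.97 ± 3.32 with 1 at the limit. Its later means lay between -0.18 and 0.09, and with limit values left out its value was -1.18 (adjusted p = 0.0557). The value of GP033F4 also moved to -1.23 without replicate 1, to -4.33 without replicate 3 and to -4.46 with the arrays scaled. With replicates 1 and 2, and 3 and 4, averaged, GP089G2 stayed past the threshold (adjusted p = 0.0259) while GP005B2 (0.0718), GP088H4 (0.203) and GP033F4 (0.18) did not. The call of GP005B2 was also lost without replicate 1, 3 or 4 (adjusted p = 0.128, 0.0599 and 0.104), that of GP088H4 without replicate 3 (0.056), and that of GP033F4 without replicate 1 or 2 (0.168 and 0.0585) and without the 10 arrays with over 100 limit values (0.116).

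**Figure D4:**
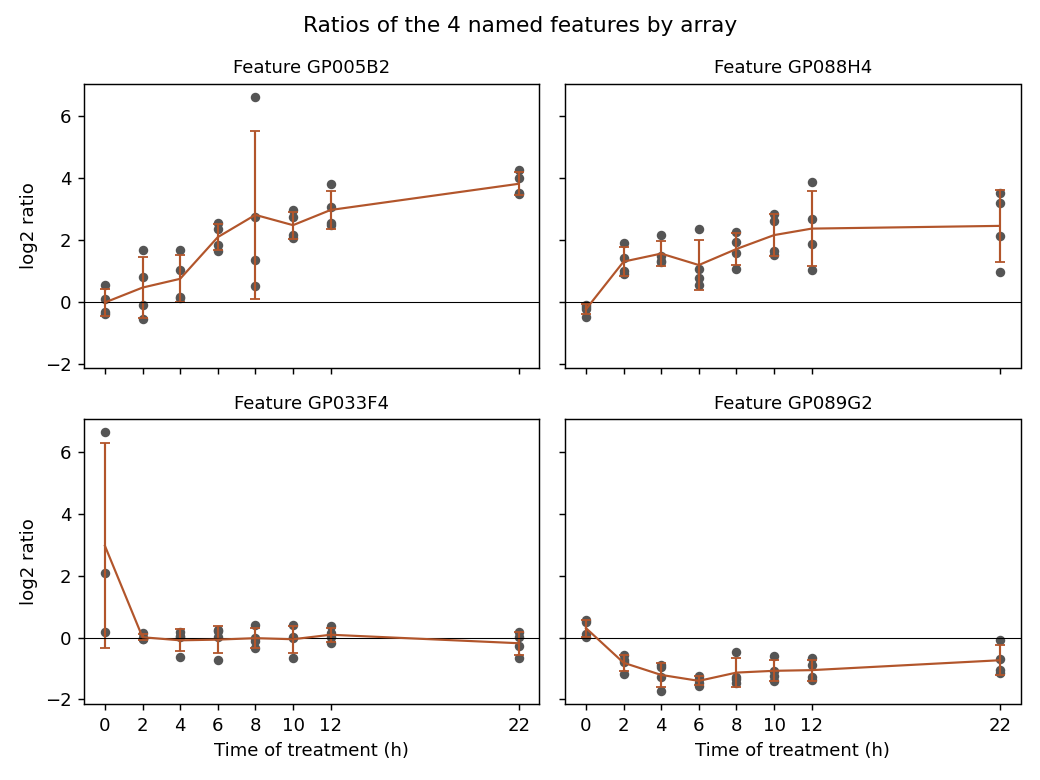
Log2 ratio (vertical axis) of the 4 named features against time of treatment in hours (horizontal axis). Points are arrays and lines with bars are the mean and SD of 4 arrays (3 at 0 h for GP033F4). GP005B2 reaches 3.82 at 22 h, GP089G2 is at -1.40 at 6 h, and GP033F4 has widely spread values at 0 h (adjusted p = 0.147 against 0), with 1 array at the limit.

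The F test over time called 169 features, of which 168 were also called at 1 or more time points and 154 at 22 h. Late ratios (10, 12 and 22 h) differed from early ratios (2, 4 and 6 h) for 194 features. In 155 of them the late ratio was above the early one, with medians of 0.74 late and 0.24 early, and in 138 of these 155 the late ratio was also the larger in size. In the other 39 the late ratio was below the early one, with medians of -0.20 and 0.13. GP005B2 was among the 155, with a difference of 1.99 (adjusted p = 0.00257). Without 1 replicate the F test called 77 to 88 features and late minus early 83 to 187. Of the 194, the side with the lower late ratio went from 39 features to 5, 9 and 8 without replicate 1, 2 or 3, to 68 without replicate 4, to 14 with no dye term, to 3 with the arrays averaged, to 5 without the 10 arrays with over 100 limit values and to 97 with the replicate block.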

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

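The tests of the upper-limit values and the splits that move arrays in pairs were chosen after the result was seen, and the counts under other groupings of single arrays were planned before. Of 79 groups of 4 arrays tested for a value far from the other 3, 7 were past Dixon's critical value, where chance gives about 1 in 20, or 3.95.

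Values at the upper limit stood apart on single arrays. Replicate 2 at 2 h had 333, replicate 2 at 8 h had 476 and replicate 1 at 6 h had 185, while replicate 1 at 6 h had 3 at the lower limit and replicate 1 at 22 h had 12 features without a value. In all, 10 arrays had 112 to 476 values at the upper limit and 7 to 25 missing values, and the other 22 arrays had 0 to 62 and 35 to 170. Features at the upper limit on 3 or more of the 10 arrays (354 features) lacked a value on 16.6% of the other 22 arrays, against 0.0859% for features never at it, a ratio of 194. This goes with features of little signal in a single channel that were recorded at the limit on some arrays and as missing on others. That channel is channel 1 if the deposited ratio was channel 2 over channel 1, and channel 2 if it was not. A difference between treated and control RNA would put a feature at opposite limits in opposite orientations, but 85.8% of the 479 features at the upper limit on at least 2 of the 10 arrays were at it in both orientations, which argues against it. No signal values were used here, so the low signal itself stays untested.

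Further results were set apart. The negative set at 12 h had a median of -0.51 on replicate 1, below its other 3 arrays, and feature GP033F4 at 2 h had 0.16 on replicate 4, above the other 3. The late minus early test called 194 features, and feature GP005B2 differed by 1.99 between late and early time points. For these features late and early effects were unequal by the test of the difference itself. The F test over time called 169, but it tests differences from 0 h. A constant response from 2 to 22 h would pass it too.

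For the counts at single time points, each array can be relabelled as to which channel held the treated RNA, which gives 8 relabellings, too few for a share under 0.05. At 0 h all 8 gave at least the real count of 0, the highest other being 18. At each later time point 1 of the 8, the real one, gave as many. The real counts were 29, 187, 308, 334, 335, 302 and 610 at 2 to 22 h, and the highest others were 1, 0, 1, 3, 2, 1 and 14. For the F test, the mean of 2 to 22 h minus 0 h and late minus early, 100 splits of the arrays within each orientation were counted, and for each of these results 1 of the 100, the real one, gave as many features. The real counts were 169, 170 and 194, and the highest of the other splits were 1, 64 and 8. This excludes chance only if the arrays of a time point are independent. With arrays 1 and 2, and arrays 3 and 4, of a time point moved together, 4 of 100 splits gave as many features for the F test and 4 of 100 for the mean, with highest others of 277 and 210, above the real counts, and 1 of 100 did for late minus early, with a highest other of 87. Late minus early then stayed above every other split drawn, which argues against chance for it. For the F test and the mean, a share of 4 in 100 drawn splits is too near 0.05 to exclude chance. Some of their splits called more features than the real one.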

How the results depend on the processing

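Chosen after seeing the data were these alternatives: limit values left out, the 10 arrays with over 100 upper-limit values left out, and features with values in 1 orientation let in. The cause of the changes was not tested unless stated. No total moved by over 1.5 times with no dye term, centring, a robust variance, limit values left out or features on all 32 arrays. Nor did leaving out each later time point move the mean of 2 to 22 h minus 0 h, the result it was run for. The random block used a consensus correlation of -0.00226, which makes it nearly the main fit again. Its unchanged totals therefore do not show that pairs of arrays can be ignored. With no dye term the negative side alone moved more, from 99 to 61 at 6 h, from 85 to 54 at 8 h and from 39 to 14 for late minus early. Turning the sign reversed the named features by construction, to -2.22 for GP005B2, -2.06 for GP088H4, 2.98 for GP033F4 and 1.37 for GP089G2. The gene list tests (camera, fry) were not run, for want of gene names, and testing each feature on its own is the main setting here. GP033F4 has no value among features on all 32 arrays or without replicate 4, as the filter removes it.

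With the arrays averaged as dye swaps, which leaves 2 values per time point, counts were 1 at 0 h, 2 at 2 h, 20 at 4 h, 88 at 6 h, 129 at 8 h, 147 at 10 h, 122 at 12 h, 358 at 22 h, 59 for the mean of 2 to 22 h minus 0 h, 66 for late minus early and 43 for the F test. Of the 358 at 22 h, 340 were among the 610. At a threshold of 0.01, counts were 8, 77, 131, 166, 204, 182 and 389 at 2 to 22 h, 96 for the mean, 91 for late minus early and 92 for the F test. Without the 10 arrays, which leaves 22, they were 0 (579 unadjusted, limma), 17, 153, 171, 141, 133 and 404 at 2 to 22 h, 62 for late minus early and 78 for the F test. The negative side then held 4, 36, 38, 34, 10 and 52 features at 4 to 22 h, against 83, 99, 85, 96, 54 and 166. The arrays left at 4 h were replicates 2 and 4, both with the treated RNA in channel 1. Those left at 10 and 12 h were replicates 3 and 4. The falls cannot be told apart from the loss of arrays and, at 4 h, of 1 orientation. With each time point fitted alone, limma estimated the spread from 4 arrays. It called 4 at 2 h, all on the negative side, and 43 at 4 h, all on the positive side. It called 0 at 6, 8, 10 and 12 h (853, 870, 576 and 1201 at an unadjusted p under 0.05). At 22 h it called 68 (67 positive and 1 negative). Scaling of arrays gave 2 at 0 h, 88 at 2 h (44 positive and 44 negative, against 16 and 13) and 129 at 6 h (99 and 30, against 209 and 99). It moved the negative side from 54 to 117 at 12 h and from 166 to 77 at 22 h, and gave 131 positive and 60 negative features for the mean of 2 to 22 h minus 0 h, against 136 and 34. Letting in features with values in 1 orientation gave 15 at 0 h. After such calls were seen, the fits on averaged arrays, without the 10 arrays and on relabelled arrays were restricted to the 10732 features tested in the main setting. The mean of 2 to 22 h against 0, without subtracting 0 h, was called for 1710 features (945 positive and 765 negative, 55.3% positive against 80.0%). It holds no error of the 0 h arrays, so its counts are not directly comparable.

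With the replicate block, the counts were 91 at 2 h, 299 at 4 h, 545 at 6 h, 564 at 8 h, 497 at 10 h, 468 at 12 h, 915 at 22 h (587 positive and 328 negative), 286 for the mean (207 and 79), 354 for late minus early (257 and 97) and 332 for the F test. The numbers were not taken to pair the arrays, since only 48 of 112 same-number pairs had a residual correlation over 0.1 (lowest -0.238). As a hint towards pairing, 19 of 32 arrays correlated best with their own number, where chance gives about 7.23, and the mean correlation was 0.0895 for the same number and -0.162 for another number of the same orientation.

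Leaving out the array of 1 replicate number at the time point itself gave 1 to 4 features at 0 h, 0 to 27 at 2 h and 58 to 141 at 4 h. It gave 155 to 217 at 6 h, 179 to 324 at 8 h, 207 to 303 at 10 h, 184 to 241 at 12 h and 443 to 645 at 22 h. For the contrasts and the F test, all arrays of a number were left out, which removes more data. That gave 115 to 134 for the mean, 83 to 187 for late minus early and 77 to 88 for the F test. Ranges of these different kinds are not comparable. Counts fell by over 1.5 times without replicate 1 at 2, 4, 6, 10 and 12 h (19, 58, 184, 207 and 184), replicate 2 at 2, 4 and 8 h (0, with 459 unadjusted by limma, 63 and 179), replicate 3 at 4 and 6 h (113 and 155) and replicate 4 at 2 and 6 h (14 and 178). They also fell so for late minus early without replicate 1, 2 or 3 (96, 100 and 83) and for the F test without any 1 replicate. Adjusted p-values over the alternatives ran from 1.21e-05 to 0.128 for GP005B2, 0.000459 to 0.203 for GP088H4, 0.000859 to 0.18 for GP033F4 and 3.32e-07 to 0.0259 for GP089G2. The correlation across features, which are not independent, of the ratios at 2 and 4 h was -0.335, and it reversed to 0.158 with limit values left out and to 0.0188 on features with all values.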

Other observations

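The tests of centring and dye bias were written before their results were seen, and the other tests here were chosen after the patterns had been seen. The 138 features beyond 2-fold on the positive side at 22 h were grouped by the correlation of their time courses, which gave 28 groups, the 3 largest with 75 features. The largest group (43 features) had median log2 ratios of 0.15 ± 0.07 (SD, n = 4) at 2 h, 0.74 ± 0.20 at 6 h, 1.34 ± 0.06 at 10 h and 2.57 ± 0.27 at 22 h. The smallest of the 3 (14 features) stood at 1.19 ± 0.41 at 2 h, 1.48 ± 0.38 at 8 h and 2.39 ± 1.11 at 22 h. At 2 h limma called 0 of these 14 features singly, with 13 at an unadjusted p under 0.05, and at 8 h it called 13. These groups were formed on the values they describe, and several of their features may hold clones of 1 transcript.

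In the group of 14 features, arrays 1 and 2 at 22 h averaged 1.503 and arrays 3 and 4 averaged 3.280. In the group of 18 features the averages were 1.78 and 0.92. Over the 942 features called at any time, the difference of arrays 1 and 2 from arrays 3 and 4 exceeded that of arrays 1 and 4 from arrays 2 and 3 at 7 of the 7 later time points, by ratios of 1.002 at 2 h and 1.13 to 1.42 at the others, and at 0 h the ratio was 0.926. Over features called at no time the median ratio was 0.942, and at 2, 4, 6, 10, 12 and 22 h the ratios were 0.970, 0.863, 0.767, 0.826, 1.02 and 0.942, which argues against a structure common to all features at these times. At 8 h the ratio of these features was 1.18, near the 1.28 of the called ones, so such a structure stays open there. The excess is consistent with dye swaps of 2 RNA pairs whose responses differed, but arrays hybridised in 2 batches would give it too, and over all features the consensus correlation within these pairs was 0.000111, below the 0.0509 of the other pairing, arrays 1 and 4 and arrays 2 and 3. The 10 arrays with over 100 upper-limit values were, except replicate 3 at 4 h, all replicates 1 or 2. A technical trait therefore followed nearly the same split. Whether the cultures differed was not tested.

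At 22 h, 72.8% of the called features were on the positive side. Without replicates 1 to 4 in turn the share was 86.2%, 81.9%, 66.2% and 61.2%. It was 64.2% with the replicate block, 83.2% with the arrays averaged, 87.1% without the 10 arrays with many limit values and 98.5% with 22 h fitted alone. Limit values left out gave 72.3%, which argues against limit values as the source of the excess. Fits on arrays of 1 orientation alone gave 84.2% of 265 calls and 90.3% of 144 calls, which argues against dye bias as the source. These fits had no dye term and called 10 and 9 features at 0 h. In the main fit the dye term was past the threshold for 3060 features. Centring gave 75.9%, but it decides nothing, since no deposited array median was further from 0 than 0.051 on the log2 scale, and the authors' normalization stays open. One hypothesis is that more transcripts on this array changed to one side than to the other. The excess is one of features, however, and several features may hold clones of 1 transcript, which was not tested. The array was enriched for flower transcripts, so the excess may come from the choice of clones, which was not tested. Which side is the dexamethasone side is likely but not settled.

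The correlation across features between the ratios at 12 and 22 h was 0.355 with limit values kept and 0.682 with them left out, and that between 4 and 8 h was -0.293 and 0.361. Limit values made up 0.982% of all values.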
